A study of Homo sapiens with 31 samples.

How the data were processed

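Total RNA was sequenced from whole thymus (2 libraries), from primary T-cell acute lymphoblastic leukaemia (T-ALL) samples (10 libraries) and from CUTLL1 and HPBALL, established T-ALL cell lines in which NOTCH signalling is active. Per the labels, each line was treated with a gamma-secretase inhibitor (GSI), which stops the release of the active NOTCH fragment, or with the vehicle DMSO, with 1 library per group. CUTLL1 cells also carried short hairpin RNAs (shRNAs) against the long noncoding RNA LUNAR1, as shLUNAR1_1 and shLUNAR1_2, or a control shRNA against Renilla luciferase, with 5 libraries per group. Libraries were strand specific and were made from either polyadenylated RNA or RNA depleted of ribosomal RNA. The labels do not say which library had which preparation, and they describe the reads both as paired-end and as single-read.

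Per the submitters' processing notes, CASAVA and TopHat were used with the human assembly hg19, and their versions are not given in the sources used here. The authors deposited a matrix of fragments per kilobase, scaled to library size (FPKM), with 1 column per thymus or T-ALL library. It holds 21821 features, of which 1984 are long noncoding features with identifiers of the submitters' own catalogue. Upper quartiles of the 12 columns lay between 12.4 and 12.9 FPKM, so the values had been scaled between libraries by a method the labels do not state. The other 4 deposited tables have the layout of Cuffdiff output and give 1 FPKM value per group. Per the file headers they also give a p-value, a q-value and, in the shRNA tables, a test statistic for each gene, all from the authors' own comparison. The shRNA tables list no long noncoding features, so no LUNAR1 level under the hairpins was analysed here. No file gives counts or totals, so the depth of every library is unknown and no counting interval was computed. The control values of the 2 shRNA tables were the same up to a constant (median log2 ratio 0.0028, 99th percentile of the deviation 1.03e-05), so both shRNA comparisons rest on the same control libraries.

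Gene symbols that had become dates in the matrix and in the shRNA tables were restored through the gene identifiers. Fold changes in the deposited tables were computed as log2 of the ratio of the 2 deposited FPKM values, because the deposited fold change field holds unreadable entries where one group is at 0. LUNAR1 has no symbol in the files. It was matched by position to the only feature between PGPEP1L and SYNM in the deposited coordinates, the order that the RefSeq annotation gives. The gap from PGPEP1L to that feature is 6861 bp in the deposited hg19 coordinates and 6911 bp to LUNAR1 in RefSeq on GRCh38.p14.

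T-ALL and thymus libraries were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean trend) on log2(FPKM + 1). Features with at least 0.5 FPKM in at least 2 of the 12 libraries were tested, and those with a Benjamini-Hochberg adjusted p under 0.05 were called. A log2 fold change from this fit is on the log2(FPKM + 1) scale and understates the change of weakly expressed genes. Gene lists, 22 in number, were tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists. Counts of called members are given over all features tested and adjusted over the list alone. P-values measure only the spread between these samples. The fit was tested on simulated data with planted changes and 14667 genes. It recovered 14.9% of genes changed by 1 on the log2 scale, 56.7% at 2 and 95.5% at 3, with 8 false calls among 119. Both simulated groups had the spread of the T-ALL libraries, and the expression filter was not applied again. Changes were planted only in genes with a mean of at least 1 on the log2(FPKM + 1) scale. The simulation leaves out the differences between the real thymus libraries, so these rates need not hold for the real comparison.

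LUNAR1 was correlated with 8 genes across the 10 T-ALL libraries as Pearson's r and Spearman's rho on log2(FPKM + 1). Each has a two-sided permutation p from 100000 permutations, adjusted over the 8 genes. In the deposited tables a gene counted as called where the authors' q was under 0.05. The counts adjusted over the list alone there use the authors' p-values. Each list's median log2 fold change over members with at least 1 FPKM in either group was placed among 10000 random lists of the same size matched on mean expression. The random lists draw genes independently and ignore correlation between members of a list, so a percentile is a description and not a test. Of 55 pairs of a list and a table, 27 lay outside the central 95% of random lists. Overlaps of calls were set beside n1 x n2 / N, a number not matched on expression. For the shRNA pair they were also set beside 200 simulations of unchanged groups that share control libraries, with errors derived from the deposited statistics and a control share of 0.5 of the variance. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

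The gene lists, tests, thresholds and the rule for named genes were chosen before the data were examined. For T-ALL against thymus the rule takes the 10 genes higher and the 10 lower with the largest fitted change among called genes with a symbol. Their T-ALL and thymus values must not overlap and their mean must reach 1 FPKM. For GSI and for shLUNAR1 it takes the 10 lower and the 10 higher with the largest mean deposited change among genes called in the same direction in both tables, with at least 1 FPKM in the higher group of each. LUNAR1, IGF1R and members of the lists are named beside these, and at most 2 long noncoding identifiers per direction. Sex-linked marker genes, receptor gene segments and ribosomal or small RNA genes are not named. The lists covered NOTCH targets, MYC and ribosome biogenesis, cholesterol synthesis, cell cycle, early T progenitors, cortical thymocytes, mature T cells, T-ALL oncogenes, IGF1R and PI3K signalling and the IGF1R locus. Others covered p53 and apoptosis, interferon response, immediate early and heat shock genes, non-polyadenylated RNA and known long noncoding RNAs. Markers of thymic epithelium, stroma and endothelium, adipocytes, B cells, myeloid and dendritic cells, erythroid cells and platelets, and NK and cytotoxic cells covered other cells a sample could hold.

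Alternatives covered the pseudocount, the filter, the scaling, array quality weights, the variance trend and leaving out each library in turn. For the deposited tables they covered a stricter q, minimum FPKM, a minimum fold change and centring. One alternative, leaving out features listed at 0 in all T-ALL libraries, was added after the data were seen. The thymus columns could be matched only to their group, and the tables hold 1 value per group, so no replicate block was fitted and no shRNA library was left out.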

Results

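The series measured RNA in whole thymus, in primary T-ALL and in T-ALL cell lines in which NOTCH signalling or LUNAR1 had been perturbed. A deposited FPKM matrix held 2 thymus and 10 T-ALL libraries. The authors' deposited tables compared DMSO with GSI in CUTLL1 and in HPBALL, and a control shRNA with each of 2 shRNAs against LUNAR1 in CUTLL1. Between 14921 and 16892 features were above 0 FPKM in a T-ALL library, and between 16763 and 17091 in a thymus library. In 1 of the 2 thymus libraries a single long noncoding feature held 95.3% of the summed FPKM, against 1.28% for the top feature of the other and 1.03 to 26.5% in T-ALL. Across features, Pearson's r of log2(FPKM + 1) was 0.929 between the thymus libraries, 0.825 to 0.946 between T-ALL libraries (45 pairs) and 0.742 to 0.902 between a T-ALL and a thymus library (20 pairs). Features are not independent replicates of such a correlation.

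The comparison of primary T-ALL with thymus asks how the leukaemic transcriptome differs from that of the organ in which T cells normally develop. In T-ALL libraries 7 of 15 cortical thymocyte genes and 6 of the 8 thymic epithelium markers that passed the filter fell. Rises were called in 5 of 12 immediate early and heat shock genes and 5 of 14 cholesterol synthesis genes. Those rises lost their calls without the thymus library dominated by a single long noncoding feature. As lists, all 4 passed the set test at its preset correlation and none did with an estimated correlation (adjusted p = 0.1205, 0.205, 0.205 and 0.205). CD8B, a chain of the CD8 co-receptor, averaged 5.91 ± 4.62 FPKM (SD, n = 10) in T-ALL against 358 and 504 in the 2 thymus libraries. RAG1, a subunit of the recombinase that assembles antigen receptor genes, averaged 27.5 ± 16.6 FPKM (SD, n = 10) against 906 and 1255. FOSB, a subunit of the AP-1 transcription factor, averaged 165 ± 112 FPKM (SD, n = 10) against 1.83 and 16.2, and the low-density lipoprotein receptor LDLR averaged 69.9 ± 56.2 FPKM (SD, n = 10) against 3.21 and 3.99.

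Of 14667 features tested with limma, 585 were called, 142 higher and 443 lower in T-ALL. Among them were 72 of 1523 long noncoding features, 21 higher and 51 lower. The unadjusted p was under 0.05 for 2786 features. In 2109 features (14.4%) no T-ALL value overlapped the thymus values, where chance gives 3.03%, and 558 of these were called. The count rested on the thymus pair. Without the library in which 1 feature held 95.3% of the summed FPKM it was 36 (1 higher, 35 lower), and without the other thymus library it was 292 (41 higher, 251 lower). It was 1395 with array quality weights and 340 with a filter on mean FPKM of at least 2.

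By the rule that named them, the 10 named genes that rose were above both thymus values in all 10 T-ALL libraries. FOSB led them at 4.27 ± 0.76 (log2, SE, adjusted p = 0.00579). RGS9, a regulator of G-protein signalling, followed at 4.06 ± 0.81 (adjusted p = 0.0123). The cytokine gene TNF rose by 3.73 and RAP1GAP2, an activator of GTP hydrolysis by the small GTPase RAP1, by 3.66. AJAP1 rose by 3.64, LDLR by 3.63 and PRKCA, a protein kinase C, by 3.47. PEX5L rose by 3.43 ± 0.44 with the lowest adjusted p of the 10 (0.000457). PPP1R15A, which directs dephosphorylation of the initiation factor eIF2 alpha under stress, rose by 3.41, and the AP-1 subunit JUN by 3.29 (404 ± 217 FPKM, SD, n = 10, against 16.4 and 69.8). Without the thymus library with 95.3% on 1 feature, AJAP1 was the only one of these 10 still called. Without the other thymus library RGS9, TNF, AJAP1 and PRKCA lost the call. The long noncoding feature XLOC_tallLncRNA_152280 rose by 3.47 (193 ± 146 FPKM, SD, n = 10, against 10.4 and 15.5) and XLOC_tallLncRNA_137813 by 3.03.

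Of the 10 named genes called lower, 4 had values above 0 in T-ALL. CD8B dropped by 6.24 ± 0.64 (log2, SE, adjusted p = 6.07e-05) and RAG1 dropped by 5.64 ± 0.90 (adjusted p = 0.00271). PRSS16, a serine protease of thymic epithelium, dropped by 5.89 ± 0.64 (adjusted p = 0.000109), from 14.04 and 263 FPKM to a mean of 0.0664. CCL25, a chemokine of thymic epithelium, dropped by 5.86 ± 0.74 (adjusted p = 0.000431). Without the thymus library with 95.3% on 1 feature RAG1 lost the call, and CD8B kept it without either thymus library. PRSS16 and CCL25 were not tested with 1 thymus library, because they then failed the filter. The other 6 were listed at 0 in all 10 T-ALL libraries and their loci all span over 200000 bp, so no fold is given and the call is not read as a fall in expression. They were ARHGAP15 (136 and 205 FPKM in thymus), MBNL1 (127 and 144), CDK6 (108 and 116), MSI2 (63.1 and 110.2), SSBP2 (73.2 and 90.03) and RUNX1 (59.5 and 72.9). MBNL1 and MSI2 encode RNA-binding proteins, CDK6 a cyclin-dependent kinase and RUNX1 a transcription factor of blood cell development. Because these 6 were listed at 0 throughout T-ALL, the 6 next genes by the same ranking were also taken, a choice made after their values were seen. They were DEFA1B, TBATA, HIST3H2BB, KRT5, CCL18 and RORC, with changes from -5.46 to -4.84. XLOC_tallLncRNA_233380 was listed at 0 in all T-ALL libraries (28.3 and 47.1 FPKM in thymus) and XLOC_tallLncRNA_021840 dropped by 4.57.

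**Figure D1:**
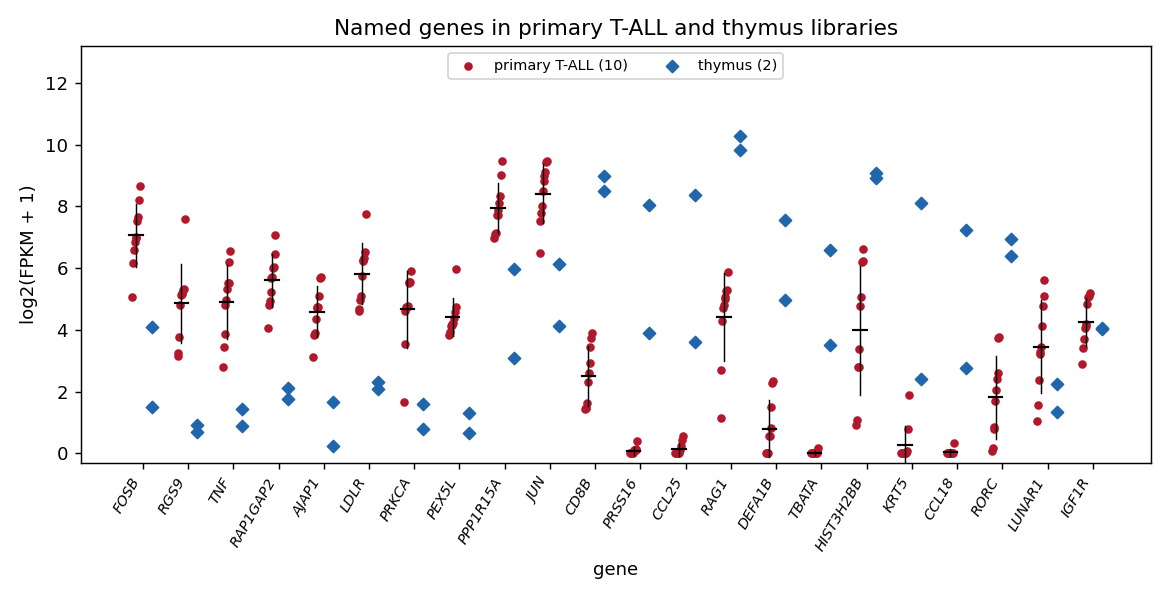
Levels of named genes, LUNAR1 and IGF1R on a log2(FPKM + 1) axis in 10 primary T-ALL libraries (red circles, with a black line for the mean and a bar for 1 SD) and 2 thymus libraries (blue diamonds). By the rule that named them, FOSB to JUN lie above both thymus values in all 10 T-ALL libraries, and CD8B and RAG1 lie below both. LUNAR1 and IGF1R, shown whatever their values, overlap the thymus values.

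Of the cortical thymocyte list, genes of the stage at which thymocytes rearrange receptor genes, 7 of 15 measured members fell and 0 rose (13 lower adjusted over the list alone). Beside CD8B and RAG1 these were RORC at -4.84, CD1C at -4.49, RAG2 at -3.85, CD8A at -3.71 and ARPP21 at -2.15. CD1A stood at -4.19 without passing (adjusted p = 0.178), PTCRA at -0.99 and CD5 at -0.71. The list's median was -2.69 (camera adjusted p = 1.33e-11, adjusted p = 0.1205 with an estimated correlation). Of the 16 thymic epithelium markers 8 passed the filter, and 6 of these 8 fell and 0 rose (7 lower adjusted over the list alone), with a median of -2.82. A marker near 0 in T-ALL could pass the filter only through both thymus libraries, so these counts and their set test lean toward a fall. The same limit holds for the stroma and endothelium markers, of which 8 of 16 passed the filter. The epithelial markers that fell are given next. They were KRT5 at -4.99, CCL25, PRSS16, KRT8 at -2.99, the thymoproteasome subunit PSMB11 at -2.65 and TP63 at -2.22, while EPCAM stood at 0.18. Their camera adjusted p was 3.65e-08, and the adjusted p was 0.205 with an estimated correlation. The 2 thymus libraries differed from each other by a median of 3.75 (log2) over the epithelial markers and 3.41 over the stroma and endothelium markers, against 0.244 over the cortical thymocyte list.

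Of the cholesterol synthesis list, 5 of 14 members rose and 0 fell (9 higher adjusted over the list alone). These were LDLR, HMGCS1 at 2.46, IDI1 at 2.0, DHCR7 at 1.92 and SREBF2, the transcription factor that drives the pathway, at 1.76. HMGCR, the rate-limiting enzyme, stood at 1.18 (adjusted p = 0.132). The list's median was 1.28 (camera adjusted p = 6.76e-08, adjusted p = 0.205 with an estimated correlation). Of the immediate early and heat shock list, 5 of 12 rose (5 adjusted over the list alone), namely FOSB, JUN, ATF3 at 3.11, FOS at 2.35 and DUSP1 at 2.11. All 5 are immediate early genes, and the heat shock genes HSPA1A and HSPH1 stood at -0.65 and -0.37. The list's median was 1.08 (camera adjusted p = 0.000124, adjusted p = 0.205 with an estimated correlation). Over this list the 2 thymus libraries differed from each other by a median of 0.317. They differed by more in FOSB (1.83 and 16.2 FPKM) and JUN (16.4 and 69.8). No rise in the cholesterol synthesis list or in this list stayed called without the thymus library dominated by a single long noncoding feature.

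Erythroid and platelet markers had the highest median of the lists at 3.40, with 0 of 12 called over all features and 7 higher adjusted over the list alone. Carbonic anhydrase CA1 stood at 5.21 (adjusted p = 0.0661) and the haemoglobin genes HBB and HBA2 at 4.62 and 3.99. The camera adjusted p was 5.72e-05, and the adjusted p was 0.329 with an estimated correlation. The non-polyadenylated RNA list was measured through 11 histone genes, of which 2 fell, HIST1H2BM at -4.09 and HIST2H3D at -2.17 (10 lower adjusted over the list alone). Its median was -2.17 (camera adjusted p = 6.76e-08, adjusted p = 0.241 with an estimated correlation), and the 2 thymus libraries differed from each other by a median of 0.939 over it.

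Of 25 cell cycle genes 1 rose, E2F1 at 1.73, and 1 fell, AURKB at -1.84 (1 higher and 8 lower adjusted over the list alone). MCM2 stood at -0.03, and the list's median was -0.87 (camera adjusted p = 0.00918, adjusted p = 0.725 with an estimated correlation). Of 13 mature T cell genes 2 fell, CD3E at -1.71 and the homing receptor CCR7 at -3.10 (3 lower adjusted over the list alone). Their median was -0.69 (camera adjusted p = 0.0153, adjusted p = 0.329 with an estimated correlation). Of 8 stroma and endothelium markers 2 fell, the collagen genes COL6A1 at -2.65 and COL6A2 at -2.75 (4 lower adjusted over the list alone), with a median of -1.53 (camera adjusted p = 0.0117, adjusted p = 0.412 with an estimated correlation). In all, 9 of the 22 lists passed with the preset correlation and 0 with an estimated one.

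The other lists did not pass. Of 16 NOTCH targets 0 were called, over all features or adjusted over the list alone, with DTX1 at 3.02 (adjusted p = 0.161) and HES1 at 1.87 (adjusted p = 0.207), and the camera adjusted p was 0.372. This list holds LUNAR1 and IGF1R, which the study itself picked, so it is not independent evidence. Of 23 MYC and ribosome biogenesis genes 0 were called, over all features or adjusted over the list alone (camera adjusted p = 0.289). Of 14 T-ALL oncogenes only HOXA7 was called, at -1.91, of 16 interferon genes STAT1 at -1.62, of 14 myeloid and dendritic markers CLEC9A at -1.70, and of 2 adipocyte markers LIPE at -1.64. Adjusted over the list alone each of these 4 lists also had 1 call, and their camera adjusted p-values were 0.697, 0.0713, 0.295 and 0.429. No member was called, over all features or adjusted over the list alone, among 12 early T progenitor genes (camera adjusted p = 0.458), 9 B cell markers (0.528), 8 NK and cytotoxic genes (0.0797), 18 IGF1R and PI3K genes (0.345), 9 locus neighbours (0.863) and 13 p53 and apoptosis genes (0.96). LUNAR1 was the 1 known long noncoding RNA measured by name or position in the matrix (camera adjusted p = 0.372).

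LUNAR1 is a long noncoding RNA downstream of IGF1R, the receptor for insulin-like growth factor 1. The series tests it as a NOTCH-dependent transcript. Its feature, XLOC_tallLncRNA_095248, spans 30762 bp at hg19 chromosome 15, positions 99557886 to 99588647. It begins 50126 bp past the end of IGF1R (99192761 to 99507759) and lies between PGPEP1L (99511459 to 99551024) and SYNM (99645286 to 99675800). In primary T-ALL LUNAR1 averaged 15.9 ± 15.6 FPKM (SD, n = 10) against 1.56 and 3.73 in thymus. It was above both thymus values in 8 libraries and below both in 1, and the difference did not pass (1.65 ± 0.96, log2, SE, limma adjusted p = 0.372). IGF1R averaged 20.7 ± 10.6 FPKM (SD, n = 10) against 15.4 and 15.6, a difference of 0.22 ± 0.51 (log2, SE, limma adjusted p = 0.846).

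Across the 10 T-ALL libraries LUNAR1 was correlated with IGF1R at r = 0.77 (permutation p = 0.0102, adjusted p = 0.0813 over 8 genes) and rho = 0.75 (permutation p = 0.0182, adjusted p = 0.146). Without the 2 libraries farthest from the median of LUNAR1, r was 0.57 in the remaining 8. The relation did not pass the adjustment, and 0 of the 8 genes passed. For the NOTCH targets and receptors r was 0.58 with NOTCH3 (adjusted p = 0.324), 0.51 with NOTCH1 (adjusted p = 0.362) and 0.40 with DTX1. It was 0.12 with HES1, 0.10 with NRARP, 0.05 with PTCRA and -0.32 with MYC. The labels give no batch for these libraries.

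**Figure D2:**
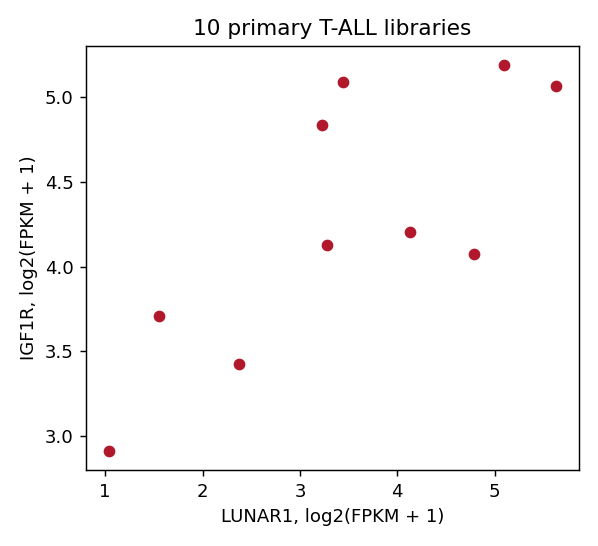
Each point is 1 of 10 primary T-ALL libraries, with LUNAR1 on the horizontal axis and IGF1R on the vertical axis, both as log2(FPKM + 1). The points rise together (r = 0.77, adjusted p = 0.0813), and r is 0.57 without the 2 libraries farthest from the median of LUNAR1.

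The GSI comparisons ask which transcripts depend on NOTCH signalling in CUTLL1 and HPBALL. Among the fixed lists with a median in the authors' deposited tables, NOTCH targets had the lowest in both lines. DTX1, a NOTCH-induced ubiquitin ligase, went from 93.5 to 11.97 FPKM in CUTLL1 and from 35.0 to 5.06 in HPBALL. The transcriptional repressor HES1 went from 31.9 to 7.30 and from 10.0 to 2.79. LUNAR1 went from 31.9 to 8.52 in CUTLL1 (log2 -1.90, authors' q = 0) and from 16.5 to 6.49 in HPBALL (log2 -1.35, authors' q = 8.02e-10). These values come from 1 library per group, so no replicate spread can be given, and the authors' q compares 2 libraries rather than 2 conditions.

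The authors' deposited table called 786 of 12763 genes tested in CUTLL1 (398 higher, 388 lower), of which 222 were long noncoding features (151 higher, 71 lower). In HPBALL it called 955 of 12459 (411 higher, 544 lower), of which 280 were long noncoding (84 higher, 196 lower). Of 11502 genes tested in both lines, 197 were called in both and 156 of these in the same direction. The 80 shared higher calls compare with 9.49 expected by chance and the 76 shared lower calls with 13.3. These expected numbers treat every tested gene as equally likely to be called, whatever its expression. With a minimum absolute log2 change of 1 the tables gave 400 calls in CUTLL1, 390 in HPBALL and 76 shared.

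The named genes that fell in both lines were IL4 (-3.66 in CUTLL1 and -4.49 in HPBALL), MYO7B (-3.58 and -2.60), DTX1 (-2.97 and -2.79), PGPEP1L (-3.09 and -2.62) and DPP6 (-3.31 and -1.49). The others were the complement receptor CR2 (-1.55 and -3.09), HES4 (-2.71 and -1.47), NOTCH3 (-2.34 and -1.82), HES1 (-2.13 and -1.84) and BMP4 (-2.66 and -1.19). IL4 encodes a T helper cytokine and BMP4 a secreted morphogen. PGPEP1L is the gene next to LUNAR1. The named genes that rose in both were NEGR1 (2.51 and 1.64), TOX2 (2.85 and 1.01), the kinase gene SGK1 (2.09 and 1.51), the MAP kinase phosphatase DUSP6 (1.79 and 1.56) and CD52 (1.59 and 1.71). RNF125 (1.94 and 1.28), the activation marker CD69 (1.06 and 1.86), CD96 (1.10 and 1.80), TENM1 (1.16 and 1.71) and CCR7 (1.43 and 1.43) completed them. Among long noncoding features XLOC_tallLncRNA_170152 (-1.68 and -2.88) and XLOC_tallLncRNA_087227 (-2.14 and -2.12) fell in both lines, and XLOC_tallLncRNA_072729 (2.12 and 0.85) and XLOC_tallLncRNA_116406 (1.34 and 1.52) rose. By size of decrease LUNAR1 ranked 15 of 880 long noncoding features in CUTLL1 and 35 of 963 in HPBALL, among those with at least 1 FPKM in the higher group.

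In CUTLL1 11 of 16 NOTCH targets fell in the authors' deposited table and in HPBALL 7 of 13, and 0 rose (13 and 9 lower adjusted over the list alone). The list's median was -2.01 in CUTLL1 and -0.87 in HPBALL, below all 10000 random lists, which ignore correlation between its members. It holds LUNAR1 and IGF1R, which the study picked, so these counts are not independent evidence. In CUTLL1 HEY1 fell by 5.06 on the log2 scale, NRARP by 3.46, HES5 by 3.42 and PTCRA, the invariant chain of the pre-T-cell receptor, by 2.18. NOTCH1 itself fell in HPBALL (-0.87). MYC stood at -0.77 (authors' q = 0.0568) in CUTLL1 and -0.65 (authors' q = 0.0979) in HPBALL. Of 23 MYC and ribosome biogenesis genes 8 fell in CUTLL1 and 5 in HPBALL, and 0 rose (19 and 6 lower adjusted over the list alone), with medians of -0.66 and -0.37. Ornithine decarboxylase ODC1 fell in both lines (-0.66 and -0.50), as did the nucleolar gene NOLC1 (-0.70 and -0.60), while NPM1 fell in CUTLL1 (-0.65).

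Around LUNAR1, IGF1R went from 29.0 to 22.9 FPKM in CUTLL1 (log2 -0.34, authors' q = 0.585) and from 16.01 to 11.1 in HPBALL (log2 -0.53, authors' q = 0.21) and was called in neither table. PGPEP1L went from 5.70 to 0.670 and from 31.1 to 5.05. Of the locus neighbours 2 of 7 fell in CUTLL1, LUNAR1 and PGPEP1L, and 3 of 9 in HPBALL, where ARRDC4 (-1.49) was the third (2 and 4 lower adjusted over the list alone, and 1 higher in CUTLL1). SYNM, on the other side of LUNAR1, stood at -1.01 (authors' q = 0.118) and -0.72 (authors' q = 0.0703).

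**Figure D3:**
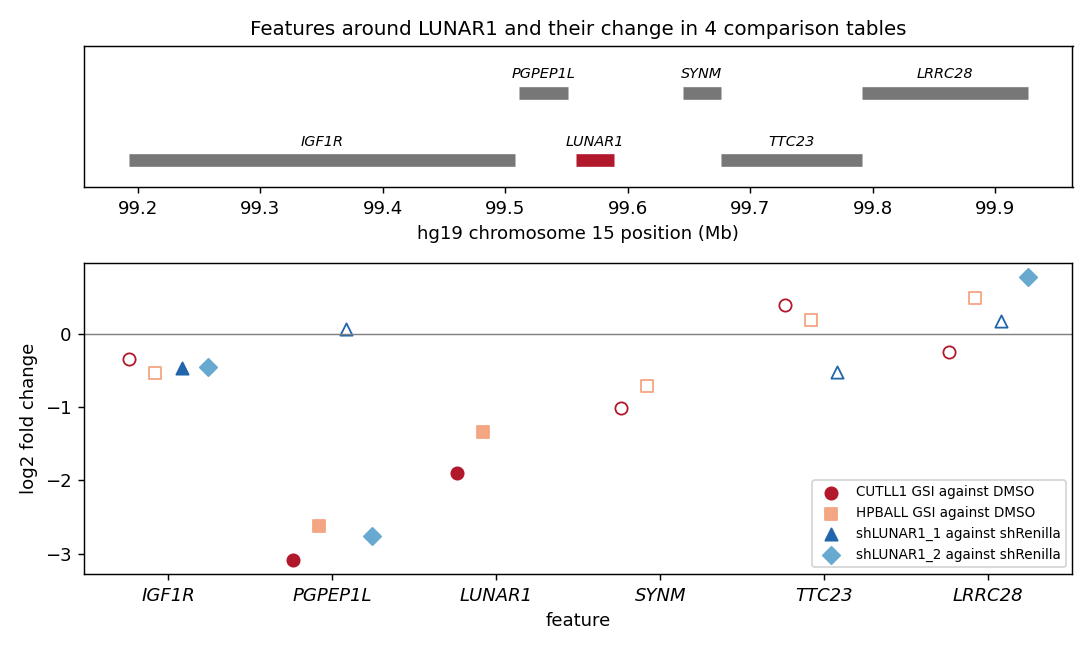
The upper panel maps IGF1R, PGPEP1L, LUNAR1, SYNM, TTC23 and LRRC28 to scale along hg19 chromosome 15 in Mb, and the lower panel gives each feature's log2 fold change in the authors' 4 deposited tables, filled where the authors' q was under 0.05. LUNAR1 (-1.90 and -1.35) and PGPEP1L (-3.09 and -2.62) are lower under GSI in both lines. IGF1R is lower under both shRNAs (-0.46 and -0.45), whose tables share their control libraries and hold no value for LUNAR1.

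The shRNA comparisons ask what changes in CUTLL1 when LUNAR1 is targeted. In the authors' deposited tables IGF1R fell under both shRNAs, from 50.4 to 36.6 FPKM under shLUNAR1_1 (log2 -0.46, authors' q = 0.000217) and from 50.5 to 36.8 under shLUNAR1_2 (log2 -0.45, authors' q = 0.00013). Most NOTCH targets fell with it, while cell cycle genes and MYC and ribosome biogenesis genes rose. MAP1B, a microtubule-associated protein, fell (log2 -3.91 and -6.61), and ANXA1, a phospholipid-binding protein, rose by 2.33 and 4.27. The tables hold 1 value per group of 5 libraries, so no spread between libraries can be given, and they do not list LUNAR1, so its depletion could not be measured from them. Both shRNAs are set against the same control libraries, so their changes, that of IGF1R included, are not independent measurements. A shift in the control libraries cannot be told apart from an effect of the hairpins.

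The authors' deposited tables called 4964 of 10596 genes under shLUNAR1_1 (46.8%, 2593 higher and 2371 lower) and 6708 of 10608 under shLUNAR1_2 (63.2%, 3504 higher and 3204 lower). With a minimum absolute log2 change of 1 these were 756 and 1606. The smallest p in these tables was 5e-05, which 2522 and 4235 genes shared. Of 10519 genes tested under both shRNAs 3944 were called under both, and 3714 of these (94.2%) in the same direction. The 1967 shared higher calls compare with 842 expected by chance and the 1747 shared lower calls with 721, and 485 were shared with a minimum absolute log2 change of 1. Part of the excess may come from the shared controls. Among 9901 genes with at least 1 FPKM in all groups 3480 calls were shared. Unchanged groups simulated against shared controls gave 38.3 on average and at most 55. No gene was changed in those simulations, so their counts cannot say what part of the excess comes from the shared controls. Across these genes the covariance of the 2 log2 fold changes was 0.245 (r = 0.70) against 0.0563 (r = 0.49) in the simulations. Genes are not independent replicates of that correlation.

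The named genes that fell under both shRNAs were MAP1B (-3.91 and -6.61), ZNF703 (-4.08 and -6.13), the neurotrophin receptor NTRK3 (-4.16 and -5.14), KLHDC7B (-3.54 and -5.27) and SYNDIG1 (-3.64 and -4.54). CPLX1 (-2.85 and -4.81), SLCO3A1 (-2.16 and -5.28), the decoy receptor for TRAIL TNFRSF10D (-3.42 and -3.99), the signalling adaptor GAB2 (-2.58 and -4.70) and SYT5 (-4.18 and -2.81) completed them. The named genes that rose were PKIB (3.11 and 3.57), ANXA1, the WNT modulator SFRP2 (2.77 and 2.52), MORN2 (2.44 and 2.57) and DPF1 (2.62 and 2.37). The others were FAH (2.39 and 2.30), cyclin E1 CCNE1 (2.05 and 2.59), the uracil-DNA glycosylase UNG (2.0 and 2.60), AKR1C3 (1.26 and 3.24) and HPDL (1.77 and 2.62). All of these values come from the authors' deposited tables.

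Of 16 NOTCH targets 14 fell under each shRNA in the authors' deposited tables, and 0 rose under shLUNAR1_1 and 1 under shLUNAR1_2, with the same counts adjusted over the list alone. HEY1 (-1.95 and -2.32), NRARP (-1.21 and -1.99), HES1 (-1.09 and -1.34) and HES4 (-1.20 and -2.17) were among those lower. The list's medians were -0.87 and -1.14, and because the study picked IGF1R these counts are not independent evidence. Of 25 cell cycle genes 22 rose and 0 fell under each (23 and 22 adjusted over the list alone), with medians of 0.78 and 1.01, among them the replication factor MCM3 (1.38 and 1.70), CCNB1 (1.08 and 1.45) and TYMS (1.27 and 1.25). Of 23 MYC and ribosome biogenesis genes 16 rose under shLUNAR1_1 and 22 under shLUNAR1_2 and 0 fell, with the same counts adjusted over the list alone and medians of 0.54 and 1.09. NPM1 (1.60 and 1.72) and NCL (1.14 and 1.39), both nucleolar, and TERT (1.64 and 2.0) rose, while MYC itself fell (-0.55 and -0.28).

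Cholesterol synthesis genes rose in 14 of 14 under shLUNAR1_1 and in 7 of 14 under shLUNAR1_2, where 2 fell, with the same counts adjusted over the list alone. Their medians of 1.03 and 0.26 lay at percentiles 100 and 82.3 of random lists. DHCR24 rose under both (1.74 and 1.43), and INSIG1 stood at 0.26 and -1.47, called under both in the authors' deposited tables. In the cortical thymocyte list 6 of 15 fell under shLUNAR1_1 and 10 under shLUNAR1_2, and 2 rose under each, with the same counts adjusted over the list alone. Its medians of -0.09 and -0.54 lay at percentiles 16.4 and 0.12 of random lists. CD8B stood at 0.06 (authors' q = 0.664) and fell by 3.08 under shLUNAR1_2, RAG1 fell under both (-1.02 and -0.93) and DNTT rose under both (0.67 and 2.20). Of 15 IGF1R and PI3K genes 6 fell under each (7 and 6 adjusted over the list alone), while 2 and 3 rose (2 and 2 adjusted over the list alone). Among those lower were the insulin receptor substrates IRS1 (-0.59 and -1.01) and IRS2 (-1.05 and -1.69). The medians of -0.08 and -0.14 lay at percentiles 19.8 and 12.4, within the central 95% of random lists, so no shift of this list was seen. Among the locus neighbours MEF2A fell under both shRNAs (-0.50 and -0.89). PGPEP1L went from 11.97 to 12.5 FPKM under shLUNAR1_1 (log2 0.06, authors' q = 0.756) and from 11.99 to 1.76 under shLUNAR1_2 (log2 -2.77, authors' q = 0.00013).

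**Figure D4:**
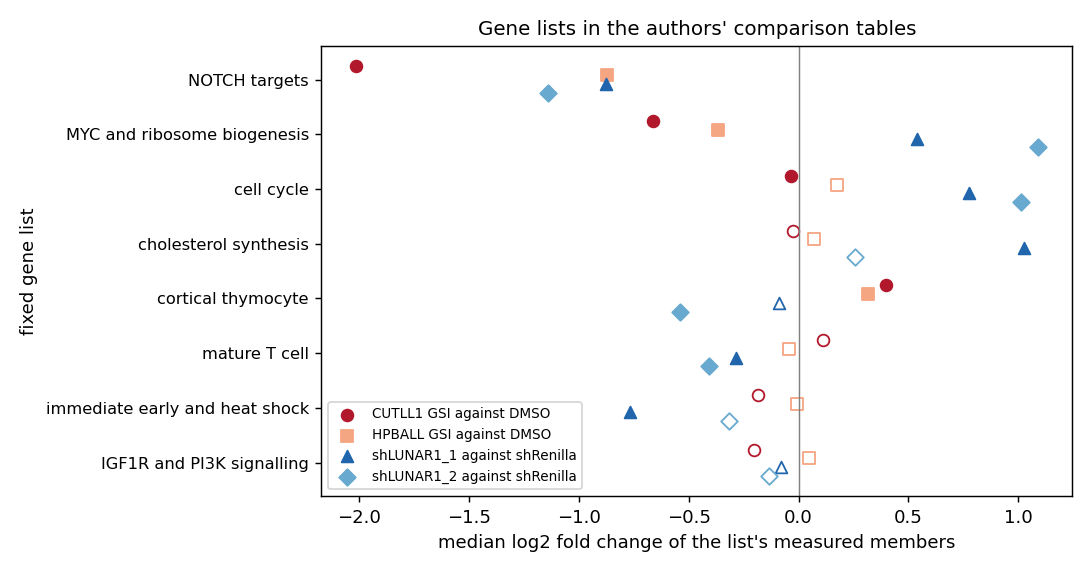
Median log2 fold change (horizontal axis) of 8 fixed gene lists (vertical axis) in the authors' 4 deposited tables, filled where the median lay outside the central 95% of 10000 random lists matched on expression. NOTCH targets are lower in all 4 tables (-2.01, -0.87, -0.87 and -1.14), and MYC and ribosome biogenesis genes are lower under GSI (-0.66 and -0.37) and higher under the shRNAs (0.54 and 1.09).

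Setting GSI beside LUNAR1 shRNA in CUTLL1 asks whether NOTCH inhibition and LUNAR1 targeting move the same genes. Of 15 NOTCH targets tested in all 3 of the authors' deposited comparisons 9 were lower in each, namely CR2, DTX1, HES1, HES4, HES5, HEY1, NOTCH3, NRARP and PTCRA. IGF1R, IL7R, MYC and NOTCH1 were lower under both shRNAs and not called under GSI, and SHQ1 was lower under GSI and not called the same way by both shRNAs. Over 10331 genes tested in all 3, 31 were higher in all and 94 lower in all. Given the genes called the same way by both shRNAs, a reference chosen after the counts were seen, 41.8 and 48.0 would be expected by chance. The shared lower calls lay above that number and the shared higher calls below it. Opposite calls lay above it too, with 82 genes lower under GSI and higher under both shRNAs (55.4 expected) and 63 the other way round (36.2 expected). Expected numbers of 18.1 and 19.6, which also treat the 2 shRNA tables as independent, are too low because those tables share controls and most calls. The 125 shared calls were 77 with a q under 0.01 and 28 with a minimum absolute log2 change of 1.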

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

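All tests weighed in this part, except the count over other splits of the libraries, were chosen only after the result was seen. Of the 66 ways to split the 12 libraries into 2 and 10, only 1, the real one, called as many as 585 genes. The highest other split called 311. A share below 1 in 66 cannot be reached here, so chance is unlikely for that count but not excluded.

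Of 26 genes and library measures examined within the 10 T-ALL libraries, 7 had 1 library far from the others, where chance flags about 1 in 20 groups. The gap between that library and its nearest neighbour, divided by the whole range, was 0.509 for RGS9, 0.58 for PEX5L, 0.642 for PRSS16, 0.577 for TBATA, 0.586 for KRT5, 1 for CCL18 and 0.518 for summed FPKM, each above Dixon's 95% critical value for 10 samples. In 4 of these genes, PRSS16, TBATA, KRT5 and CCL18, at least 5 of the 10 libraries were at 0, which sets the low end of the range. The chance rate does not hold for values piled up at 0, so the 7 do not show an excess of outlying libraries.

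Under GSI, 41 genes were called in both lines in opposite directions in the authors' deposited tables. The growth arrest gene GAS1 was at -1.86 in CUTLL1 and 1.07 in HPBALL and GADD45A at -1.06 and 1.31, while C7orf53 was at 1.24 and -0.97 and BICD1 at 0.60 and -0.99. Under the shRNAs, 230 genes were called in opposite directions, among them the histone gene HIST1H4D (1.15 and -1.33), ETV4 (-1.10 and 1.61), MDK (-1.08 and 1.22), the fatty acid desaturase SCD (1.07 and -1.06), the metallothionein MT2A (-0.98 and 1.25) and CDH4 (0.97 and -3.39). Neither set of differences was tested.

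Of 5699 features above 10 FPKM in both thymus libraries, 9 were listed at 0 in all 10 T-ALL libraries (ARHGAP15, MBNL1, CDK6, MSI2, SSBP2, RUNX1, MSH3, DHFR and 1 long noncoding feature). Their median locus span was 261498 bp against 34254 bp for all 5699, at percentile 100 of 10000 random sets, and all 9 were among the 355 features over 200000 bp. Of the 5699 features 0 had a highest T-ALL value above 0 and at most 0.1 FPKM. This is consistent with estimates left out at long loci in the T-ALL columns. Loss of expression would not be limited to long loci, yet 0 of the 5344 features up to 200000 bp were listed at 0 in all T-ALL libraries. For these 9 features the values argue against loss of expression in the leukaemic cells as the source of the zeros. The lowest of the 9 was at 16.2 FPKM in the DMSO libraries of the lines, but the lines are other cells.

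Thymic epithelium markers were lower in T-ALL, and epithelial cells in whole thymus are a candidate source. Those markers differed between the 2 thymus libraries as a block (absolute median log2 ratio 3.75, percentile 100 of random lists). PRSS16 at 14.04 and 263 FPKM and CCL25 at 11.3 and 329 FPKM were among the most abundant of them. The stroma and endothelium, myeloid and dendritic, erythroid and platelet, and non-polyadenylated RNA lists also reached percentile 100. Among these, erythroid and platelet markers had a higher median in T-ALL (3.40). A difference between the thymus libraries therefore cannot decide why the epithelial markers were lower in T-ALL. For the lower cortical thymocyte list, tumour maturation stage and sample handling stay open, and neither was tested. Sample handling also stays open for the higher immediate early genes and was not tested.

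MYC and ribosome biogenesis genes were higher under both LUNAR1 shRNAs and more so under shLUNAR1_2. Centring moved the lower of the medians only from 0.54 to 0.53 and moved all other genes as little, so it decides nothing about scaling between groups. Whether the rise common to both, 0.54 at the lower, comes from the control libraries cannot be told apart from an effect of the hairpins, since the tables hold 1 value per group. Effects of the hairpins on other targets and an effect of LUNAR1 itself may both contribute, and neither was tested.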

How the results depend on the processing

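The one alternative chosen only after the data were seen left out features listed at 0 in all T-ALL libraries, and it gave 554 calls between T-ALL and thymus instead of 585. Of the values that answer a comparison, 82 stayed within 1.5 times the reported count or kept their direction and side of the threshold, and 17 moved. The 82 include counts under centring of the deposited tables. Centring cannot change how many genes are called there or a list's percentile, so those counts say nothing about robustness. The 17 include the covariances of the shRNA fold changes, which were counted as moved at any change in size. No count or single-gene change reversed, but with members of at least 0.1 FPKM counted 5 of the 55 list medians in the deposited tables changed sign. These were interferon genes under shLUNAR1_2 (0.59 to -0.02), locus neighbours under shLUNAR1_1 (0.06 to -0.46), p53 and apoptosis genes in CUTLL1 (-0.18 to 0.05) and, in HPBALL, mature T cell (-0.04 to 0.23) and early T progenitor genes (-0.04 to 0.02). Centring turned 1, cholesterol synthesis in CUTLL1 (-0.03 to 0.01). Of the values for single named genes 399 stayed on their side of the threshold and 15 were no longer called. Calls between T-ALL and thymus were 340 with a mean FPKM of at least 2, a filter that also tested fewer features, and 1395 with array quality weights. Leaving out 1 library gave 36 to 668 calls, namely 36 and 292 without a thymus library and 462 to 668 without a T-ALL library. The lowest, 36, left out the thymus library with 95.3% of its summed FPKM on 1 feature, and 33 of its calls were among the 585. In that fit the lone thymus library was assumed to vary like the T-ALL libraries. Of the 20 named genes only 12 were tested in the fits with 1 thymus library, because genes near 0 in T-ALL then failed the filter, and 10 and 4 of the 12 lost the call. RGS9 lost it with a pseudocount of 5. Of the gene lists 0 passed with an estimated correlation in place of 9. LUNAR1 in T-ALL against thymus ranged from 1.21 to 2.10 and IGF1R from 0.12 to 0.37 when 1 library was left out, and neither was called.

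In the authors' deposited tables a q under 0.01 gave 512 calls in CUTLL1 and 522 in HPBALL under GSI, and 77 shared by GSI and both shRNAs. A minimum absolute log2 fold change of 1 gave 400 calls in CUTLL1, 390 in HPBALL, 756 under shLUNAR1_1 and 1606 under shLUNAR1_2. It gave 76 shared by both lines, 485 shared by both shRNAs and 28 shared by GSI and both shRNAs. These follow from the stricter threshold itself. The covariance of the shRNA fold changes was 0.207 with an FPKM of at least 5 and 0.203 with a pseudocount of 1, against 0.245. For the array weights, the estimated correlation and the covariance the cause was not tested.

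No paired analysis was possible because the numbers on the thymus columns do not map to the replicate numbers of the labels and the shRNA tables hold 1 value per group. For the same reason no shRNA library was left out. The planned value for LUNAR1 under the shRNAs could not be given, because those tables list no long noncoding feature. Depth is unknown for every library, so its effect on weakly expressed features could not be assessed.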

Other observations

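In this part the direct comparison of the shRNA groups, the histone levels and the crossing of GSI with shRNA calls by gene list were chosen only after the results were seen, and the counts per gene list were planned. In the authors' deposited tables, of the interferon response genes 5 of 10 fell and 2 rose under shLUNAR1_1, and 6 of 12 rose and 3 fell under shLUNAR1_2, with the same counts adjusted over the list alone. MX2 (-1.64 and -3.20) and ISG15 (-1.64 and -1.54) fell under both and IFI44 rose under both (1.55 and 2.18). The list's median was -0.73 under shLUNAR1_1 and 0.59 under shLUNAR1_2, and with members of at least 0.1 FPKM counted these were -0.53 and -0.02, so the direction under shLUNAR1_2 rests on the filter. Set directly against each other as shLUNAR1_2 minus shLUNAR1_1, the shRNA groups differed by -0.85 over cholesterol synthesis genes (percentile 0 of random lists). The groups differed by -0.78 over histone genes (percentile 0.01), -0.29 over cortical thymocyte genes (percentile 0.51) and -0.25 over NOTCH targets (percentile 1.59). They differed the other way over MYC and ribosome biogenesis genes (0.53, percentile 100), interferon genes (0.56, percentile 99.97, members with at least 1 FPKM in any group) and immediate early and heat shock genes (0.35, percentile 99.4). Of the immediate early and heat shock genes 7 of 11 fell under shLUNAR1_1 and 5 under shLUNAR1_2, where 1 rose, with the same counts adjusted over the list alone, and FOSB (-3.16 and -1.95) and EGR1 (-1.30 and -0.95) fell under both. Of the p53 and apoptosis genes 5 of 11 fell under each shRNA, and 3 rose under shLUNAR1_1 and 2 under shLUNAR1_2 (5 and 6 lower, and 3 and 2 higher, adjusted over the list alone). MDM2 (0.29 and 0.31) and BCL2L1 (0.24 and 0.38) rose under both, and CDKN1A rose under shLUNAR1_1 (1.01) and stood at 0.04 under shLUNAR1_2. TP53INP1, a p53-induced gene, fell under both (-1.92 and -3.44), as did GADD45A (-0.49 and -1.93). Among 13 mature T cell genes 7 and 8 fell and 2 and 3 rose (8 and 8 lower, and 2 and 3 higher, adjusted over the list alone). The co-stimulatory receptor CD27 fell (-1.09 and -2.20) and the homing receptor SELL rose (1.40 and 1.91).

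Under GSI the cortical thymocyte list had a median of 0.40 in CUTLL1 and 0.31 in HPBALL, at percentiles 100 and 99.9 of random lists. RAG2 rose in both lines (0.76 and 0.75), and CD8B and RORC rose in HPBALL (0.99 each), while PTCRA, also a NOTCH target, fell in CUTLL1. Over all genes 1 of 14 rose and 1 fell in CUTLL1 and 3 of 14 rose in HPBALL (3 higher and 2 lower, and 3 higher, adjusted over the list alone). Of the known long noncoding RNAs 2 of 11 rose and 3 fell in CUTLL1 and 3 of 10 fell in HPBALL (3 higher and 4 lower, and 3 lower, adjusted over the list alone). Beside LUNAR1, PVT1 (-0.74) and SNHG15 (-0.63) fell in CUTLL1, TUG1 (-0.51) fell in HPBALL, and MIAT rose in CUTLL1 (0.45) and fell in HPBALL (-0.55). That difference between the lines was not tested. The PI3K catalytic subunit gene PIK3CG rose in both lines (0.81 and 0.59). Histone genes rose in HPBALL in 5 of 11 (11 adjusted over the list alone), among them HIST2H3D (1.31) and HIST1H2BK (0.99), and 0 of 11 were called in CUTLL1, a difference that was not tested.

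The MYC and ribosome biogenesis list moved in opposite directions under GSI and under LUNAR1 shRNA in CUTLL1. Of 23 genes, DKC1, NOLC1, NPM1 and ODC1 were lower under GSI and higher under both shRNAs, and another 11 were higher under both shRNAs without a call under GSI. PGPEP1L, next to LUNAR1, fell under GSI in both lines and under shLUNAR1_2 (-2.77) and stood at 0.06 under shLUNAR1_1.

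Levels of the 11 measured histone genes, whose transcripts mostly lack a poly(A) tail, differed between sets of libraries. Their median was 5134 FPKM in the DMSO library of CUTLL1, 2116 in that of HPBALL and 166 in the control shRNA libraries, which are also CUTLL1 cells. It was 857 FPKM in primary T-ALL and 3049 in thymus. The labels name 2 kinds of RNA selection without saying which library had which.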
